A study of Escherichia coli with 12 samples.

How the data were processed

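ChIP-exo, chromatin immunoprecipitation followed by exonuclease digestion, was run on Escherichia coli K-12 MG1655. Per the labels' protocols, cells were grown at 37 °C, cross-linked in 1% formaldehyde for 25 min, lysed and sonicated. The pulled-down DNA was trimmed on the beads with lambda exonuclease and RecJ exonuclease, so that read ends lie close to the cross-linked protein. The labels give 12 libraries in 6 groups of 2. Cra with an 8myc tag was pulled down with an anti-myc antibody from cells on glucose, fructose or acetate, and RpoB, the beta subunit of RNA polymerase, from wild-type, Δcra and Δcrp cells on acetate. No untagged, mock or input library was used here.

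The deposited values are the read coverage at each base on each strand, a raw signal in whole numbers with no normalization by the authors that the values show. Bowtie 1.0.0 and the genome build ASM584v2 are named in the submitters' processing notes, and filters on mapping are not given in the sources used here. Positions count from 0 and bases without reads are not listed. The signal steps gave a read length of 31 bases for Cra and 101 bases for RpoB, and the number of reads was estimated as the summed coverage over that length. The highest position puts the length of the sequence at 4639675 bp. The last gene of the gene table used for names (assembly ASM584v2) ends 1953 bp past that length, so the sequence behind the files differs from that assembly. Coordinates are therefore those of the files, written from 1, and none is taken from the table. Gene names were placed by sliding the table along the files in windows of 150 kb. Intergenic stretches were matched to locally high RpoB signal, which gave 3 segments. The offset of the second, 788 bp, came from this signal. That of the third, 1978 bp, was set by the coverage gap at crp in the Δcrp libraries, where the signal gave 1998. The first was set to 0, within the bounds of the gap at cra in Δcra, where the signal gave -17. The offsets so differ by 788 and 1190 bp. Of 4651 genes, 4643 were placed, and 8 within 200 bp of a change of offset were left out. The table gives no strand, so a gene counted as next to a region when either of its ends lay within 300 bp of the region or inside it.

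All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, tests across regions or genes with limma 3.58.1 in R 4.3.3, and plots with matplotlib 3.10.9. For Cra, both strands were summed in bins of 100 bp and divided by the library's median bin. A bin counted as bound at an enrichment of at least 5 in both libraries, bound bins at most 200 bp apart were merged, and bins over rRNA genes were left out. This is a rule without a p-value. The regions of the 3 carbon sources were merged into a union set of 317. The same libraries chose and tested the regions, so a region bound on 1 carbon source alone leans toward higher signal there. Each region's mean signal was scaled by the library's median bin outside all regions. For RpoB, the mean signal was taken over gene bodies of at least 150 bp without rRNA and tRNA genes, 4295 genes in all, and scaled by the median of ratios. Genes under 0.5 times the median bin were left out, as were 3 genes that are or overlap the deleted genes, which left 3522. Coverage is not a count of reads, so limma with a trend was used in place of a count test, on log2(scaled signal + 0.1 times the median bin). Fold changes are on that scale, which understates changes of low features. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05. The 6 Cra libraries entered one fit, and the 5 distinct RpoB libraries another.

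The design, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined. Plans that needed gene strand were changed. The list test on Cra regions was planned on gene starts, and the joined test on first genes downstream of a region. Both took either gene end instead, so genes that only end near a region count too. Runs of neighbours were planned on the same strand and here ignore strand. Named genes were, per RpoB comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with both libraries of one group above those of the other and at least the median signal, at most 1 per run of neighbours under 100 bp apart. To these came up to 4 members of each list by adjusted p and a fixed set (cra, crp, ppsA, pck, fbp, aceB, icd, pfkA, pykF, fruB, ptsH, gapA, edd, adhE, acs). Named Cra regions were the 10 most enriched per carbon source, the 10 largest changes per direction and comparison, and those next to the fixed set. Other genes and regions named were chosen after their values were seen and serve as members of a count.

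The 19 lists were glycolysis, gluconeogenesis and malic enzymes, acetate use and glyoxylate shunt, the TCA cycle, the phosphotransferase system, Entner-Doudoroff and pentose phosphate, textbook Cra-repressed, Cra-activated and CRP-activated genes, flagella and chemotaxis, ribosomal proteins, respiratory chain and ATP synthase, amino acid biosynthesis, general stress (RpoS), anaerobic and mixed-acid fermentation, fatty acid degradation, iron uptake, peptide and amino acid transport, and heat shock. For RpoB they were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists share genes, so their results are not separate evidence. For example, pgk, fbaA, gapA and eno are in both glycolysis and Cra-repressed, and ppsA and fbp in both gluconeogenesis and Cra-activated. Counts for RpoB cover only the tested members. These were 55 of 82 CRP-activated, 9 of 46 flagella and 7 of 12 fatty acid degradation genes, for example. For Cra, members next to a region were compared with all other genes by a two-sided Fisher's exact test, adjusted over lists and carbon sources. Both data sets were joined with the same test and with 10000 random gene sets.

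The limma step was tested on simulated data with known changes. The noise of each gene or region had the same fitted spread in every library, the lone wild-type one included. Differences in spread between groups were not simulated, so recovery and false calls in the data may differ. With 200 of 3522 genes changed, 100% of changes of log2 1 were recovered for Δcra against wild type with 17 false calls, 99% for Δcrp against wild type with 15, and 100% for Δcra against Δcrp with 27. With 40 of 317 regions changed, 65% of changes of log2 1 were recovered for acetate against glucose with 0 false calls, and 75% for fructose against glucose and for acetate against fructose, with 3 and 4. Changes of log2 2 were recovered at 100% in every comparison. Alternatives tried were other enrichment thresholds, bins, scalings, filters, pseudocounts, gene-body limits, a correction for distance from the replication origin, a replicate block, only the groups compared, and each library left out in turn. A search for the Cra motif was not made, because no genome sequence was used here.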

Results

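Binding of Cra and occupancy of RNA polymerase were mapped in Escherichia coli K-12 MG1655 growing in minimal medium. Cra, the catabolite repressor/activator, is a DNA-binding regulator of central carbon metabolism that fructose phosphates release from DNA. CRP, the cAMP receptor protein, activates many genes for carbon sources other than glucose. The 6 Cra libraries covered glucose, fructose and acetate at 0.2%, with 2 libraries each. The RpoB libraries were labelled as 2 each from wild-type, Δcra and Δcrp cells on acetate. Both wild-type files held identical values (0 positions differed, against 8847163 between the Δcra libraries and 8765851 between the Δcrp libraries), and per the file headers both carry the same track name. They were counted as 1 library, so wild-type values have no SD. The design text calls the Cra cultures biological duplicates. Nothing says that the RpoB libraries came from separate cultures, so their p-values measure only the spread between these libraries, which may be technical.

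Estimated depth was 2455419 and 2907164 reads on glucose, 2601573 and 1851236 on fructose, and 3052702 and 2151952 on acetate. It was 3721300 reads for wild-type RpoB, 4797482 and 4287441 for Δcra, and 4181500 and 4542256 for Δcrp. The acetate Cra libraries covered 53.6% and 55.0% of bases, against 94.0% and 95.1% on glucose and 88.5% and 88.3% on fructose. Their background was sparser: the 10th percentile of bins lay at 0.0282 and 0.0510 of the median, against 0.444 and 0.455 on glucose. Across regions, the replicates' log2 signals correlated at 0.937 on glucose, 0.943 on fructose and 0.920 on acetate, and across genes at 0.982 for Δcra and 0.994 for Δcrp. Regions and genes are not independent replicates.

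The deleted genes were examined first. RpoB signal over cra was 2.76 times the median bin in wild type, 1.74 and 1.72 in Δcrp, and 0.0456 and 0.0605 in Δcra. Almost no reads fell on positions 88034 to 89009 in either Δcra library. Over crp the signal was 5.71 in wild type, 4.99 and 5.53 in Δcra, and 0.147 and 0.122 in Δcrp. The stretch with almost no reads in crp spanned positions 3484370 to 3484749 in Δcrp replicate 1 and 3484165 to 3484752 in replicate 2. Both deletions matched their labels. The place of crp was set by its own gap, so its low signal in Δcrp is partly built in. The RpoB signal between genes alone gave a nearby offset, 1998 in place of 1978 bp.

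The first comparison asked where Cra binds on each carbon source. On glucose the most enriched bin lay between cysK and ptsH (region 2530301 to 2532000), upstream of the phosphotransferase genes ptsHI-crr, at 886 ± 2.04 times the median bin (SD, n = 2). On fructose and on acetate it lay by fruB (region 2258701 to 2262000), the first gene of the fructose phosphotransferase operon, at 956 ± 32.5 and 5388 ± 847, after 787 ± 9.11 on glucose. Strong signal also lay by epd, an erythrose phosphate dehydrogenase gene (478 ± 17.5 on glucose, 249 ± 5.76 on fructose and 780.0 ± 157 on acetate), by pfkA, phosphofructokinase (171 ± 2.75, 38.4 ± 1.33 and 343 ± 46.0), and between tnaB and mdtL (305 ± 0.125, 305 ± 19.2 and 497 ± 161). Regions by gapA, pykF, glk, adhE, edd, icd, ppsA, fbp, aceB and crp were bound on at least 1 carbon source. tRNA genes were also among the most enriched, with 69.5 ± 4.38, 104 ± 17.7 and 101 ± 22.8 at the hisR cluster.

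By the enrichment rule, 204 regions were bound on glucose, 197 on fructose and 283 on acetate, covering 62.3, 59.5 and 86.7 kb. Merged into the union set, these were 192, 182 and 273 regions, for which the summit was taken over all 3 carbon sources. That summit lay inside a gene in 91, 85 and 142 of the merged regions. A gene among the top 5% of wild-type RpoB signal lay in 66, 67 and 98, and a tRNA or rRNA gene in 32, 33 and 31. In the union of 317 regions, 140 were bound on all 3 carbon sources, 96 on acetate alone, 19 on glucose alone and 12 on fructose alone. A further 20 were shared by glucose and acetate, 17 by fructose and acetate, and 13 by glucose and fructose. Of the 96 on acetate alone, 86 stayed under 10-fold enrichment. The counts depend on the threshold, with 495, 458 and 669 regions at 3-fold and 83, 75 and 128 at 10-fold. With a single library deciding, acetate had 449 regions without acetate replicate 1 and 506 without replicate 2.

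**Figure D1:**
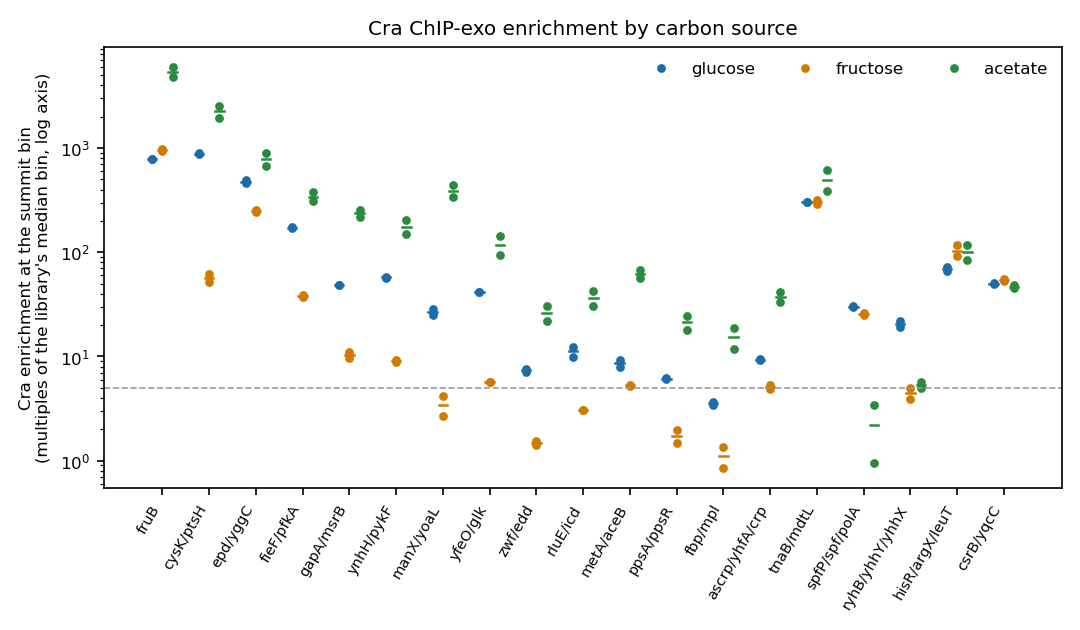
Enrichment of Cra signal in the summit bin of 19 regions, as multiples of the library's median bin on a log axis, with 1 point per library and a bar at the mean, coloured by carbon source; the dashed line marks the threshold of 5. Signal by ptsH, manX and pykF is lowest in the fructose libraries, while signal by fruB is highest on acetate.

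Members of some of the fixed gene lists lay next to Cra regions more often than other genes. Of the textbook Cra-repressed genes, 12 of 20 lay next to a region on glucose, 11 on fructose and 12 on acetate (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 3.81e-06, 2.67e-05 and 3.54e-05). For the 7 Cra-activated genes the numbers were 5, 3 and 6 (Fisher's exact test, adjusted p = 0.00199, 0.0841 and 0.00043), and with regions of at least 10-fold enrichment 0, 0 and 6, which ended the call on glucose (Fisher's exact test, adjusted p = 1). For the 14 glycolysis genes they were 7, 7 and 8 (Fisher's exact test, adjusted p = 0.00209, 0.00203 and 0.00174), and on fructose 2 at 10-fold, which did not pass (adjusted p = 0.444). TCA cycle genes reached 2, 6 and 11 of 18 (Fisher's exact test, adjusted p = 1, 0.0332 and 6.14e-05), and 0, 0 and 6 at 10-fold. The fructose call on TCA genes was lost there (Fisher's exact test, adjusted p = 0.917) and with genes within 150 bp (adjusted p = 0.0613). Ribosomal protein genes, which are highly transcribed, lay next to a region in 43, 43 and 48 of 54 cases (Fisher's exact test, adjusted p = 6.03e-30, 4e-30 and 1.5e-32), and in 15, 34 and 37 at 10-fold. None of the 46 flagella genes did (Fisher's exact test, adjusted p = 0.0248, 0.0248 and 0.00476), a call lost on each carbon source at 10-fold (adjusted p = 0.444, 0.444 and 0.189), and on glucose and fructose within 150 bp (adjusted p = 0.0557 for both). CRP-activated genes, with 4, 5 and 10 of 82, did not pass (Fisher's exact test, adjusted p = 0.121, 0.275 and 0.741). In all, 20 pairs of list and carbon source passed, and 13 at 10-fold. Genes of an operon are neighbours and not independent.

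On acetate, a gluconeogenic carbon source, Cra signal was higher than on glucose at most textbook targets. By manX, of the mannose phosphotransferase system (region 1899701 to 1900200), summit enrichment was 27.0 ± 2.66 on glucose and 389 ± 73.9 on acetate, and the region's signal rose by log2 3.55 (SE 0.19, limma adjusted p = 0.000107). Signal at fruB rose by log2 2.19 (SE 0.18, limma adjusted p = 0.000254), at gapA by 1.91, at aceB, malate synthase of the glyoxylate shunt, by 2.03, at ppsA, phosphoenolpyruvate synthase of gluconeogenesis, by 1.58, at icd, isocitrate dehydrogenase, by 1.33, and at crp by 1.71. Large rises also lay at tnaA, tryptophanase (log2 3.67), between rbsD and kup (3.39), and over the galactitol genes gatBAC (3.05). The region by adhE, alcohol dehydrogenase, had 75.2 ± 1.01 on glucose and 71.9 ± 13.9 on acetate (log2 0.02, adjusted p = 0.959). Among regions that fell were spf, encoding a small RNA (30.0 ± 0.384 to 2.19 ± 1.76, log2 -3.02), fes, of iron uptake (-3.32), ygaM/nrdH (-2.19) and ryhB, an iron-responsive small RNA (-1.97).

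Of 317 regions, 148 were higher on acetate than on glucose, 24 were lower and 145 did not pass (limma, median log2 0.52, median SE 0.21). At least 2-fold changes numbered 97 and 11. The 96 regions bound on acetate alone gave 80 of the 148 rises and 0 falls. They entered the set by their signal in these acetate libraries, so their rises are no separate support. The 15 regions next to textbook Cra genes had a median log2 of 1.42, with 12 higher and 0 lower, and kept that sign with 1.13 (11 higher and 0 lower) under scaling to total signal and 0.93 (11 and 2) to the median of ratios. The 102 regions with highly transcribed genes had a median of 0.54, with 49 higher and 3 lower, and 0.26 (37 higher and 8 lower) and 0.06 (28 and 16) under those scalings. Without acetate replicate 1 these regions had 39 higher and 6 lower, and 1 was lower without fructose replicate 1 or glucose replicate 2. The 35 regions with tRNA or rRNA genes had a median of -0.04, and 1 was higher and 1 lower, with 9 and 16 lower under those scalings. Their median was 0.09 without acetate replicate 2, 0.14 without glucose replicate 2 and -0.21 without glucose replicate 1, with 3 higher and 1 lower, 3 and 0, and 1 and 7. The balance depends on the scaling, because it moves the median of all regions from 0.52 to 0.24 with total signal and to 0.04 with the median of ratios. The splits were then 106 higher and 42 lower, and 83 higher and 64 lower.

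On fructose, signal at most textbook targets was lower than on glucose, while fruB stayed high. By ptsH it fell by 3.16 on the log2 scale (SE 0.18, limma adjusted p = 0.000265), from a summit of 886 ± 2.04 to 57.1 ± 7.67. By glk, glucokinase, the log2 change was -2.71, by yejG -2.34, by pykF, pyruvate kinase, -2.25, by manX -2.18, by edd, of the Entner-Doudoroff pathway, -1.88, by pfkA -1.87, by ppsA -1.85, by epd -0.79 and by adhE -0.85. At fruB it was 0.11 (limma adjusted p = 0.784) and at aceB -0.37 (adjusted p = 0.246), neither past the threshold. A region by fruA (region 2257801 to 2258000) was among the few that rose (2.03 ± 0.419 to 6.42 ± 0.0497, log2 1.66), as were gatBAC (0.81), sdhC (0.91) and cyaR (1.09).

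Of 317 regions, 9 were higher on fructose than on glucose, 40 were lower and 268 did not pass (limma, median log2 0.03). Next to textbook Cra genes 1 of 15 was higher and 11 lower, with a median of -1.10, and -0.97 and -1.11 under scaling to total signal and to the median of ratios. Total signal moved the median of all regions to 0.16 and gave 19 higher and 39 lower, and the median of ratios gave 14 and 44. Higher and lower regions numbered 3 and 27 without fructose replicate 1, 0 and 22 without fructose replicate 2 (limma, 26 higher at unadjusted p under 0.05), 2 and 39 without glucose replicate 1, and 14 and 44 without acetate replicate 1. Next to textbook Cra genes 7, 6 and 7 were lower without fructose replicate 1, fructose replicate 2 and glucose replicate 2.

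**Figure D2:**
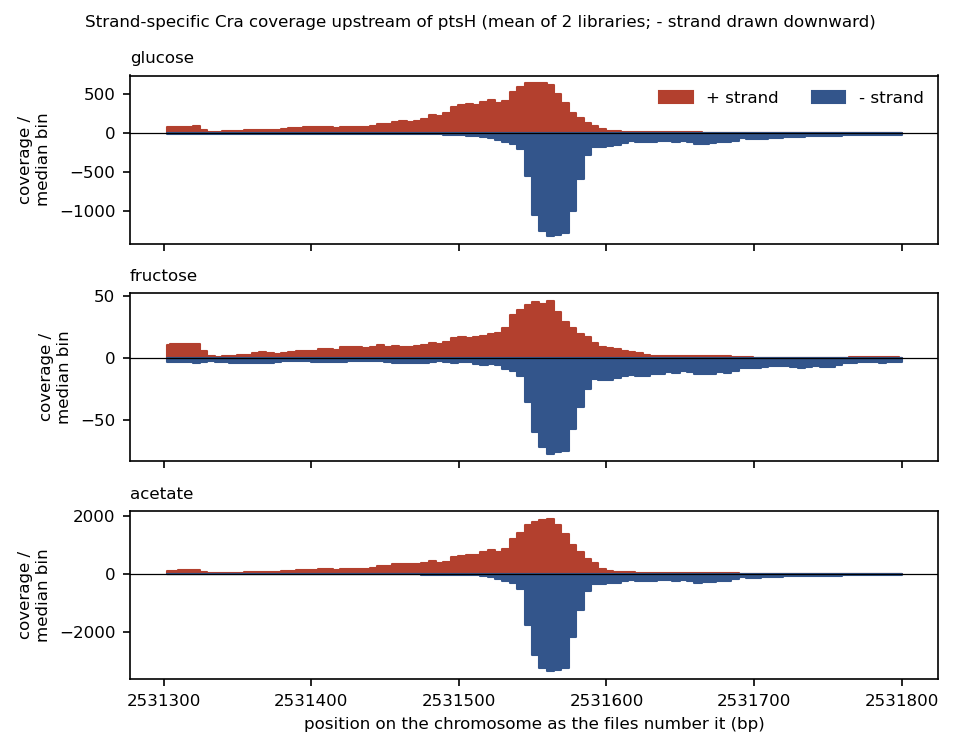
Cra coverage upstream of ptsH at positions 2531300 to 2531800 as multiples of the median bin, by strand, as the mean of 2 libraries, with 1 panel per carbon source and a different vertical scale in each. The summit bin stands at 886 on glucose, 57.1 on fructose and 2243 on acetate.

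Acetate was also compared with fructose. Signal rose by log2 5.73 at manX (SE 0.19, limma adjusted p = 6.46e-06), 4.65 at yejG, 4.35 at ptsH, 4.33 at marR, 4.13 at glk, 3.98 at nikA, 3.67 at pykF, 3.43 at ppsA and 3.10 at fbp, fructose bisphosphatase. It fell at spf (log2 -2.88), proP (-1.57), fes (-1.36) and thrL (-0.87). Between tnaB and mdtL the change was 0.56 (limma adjusted p = 0.0981), and at the small RNA gene csrB -0.27 (adjusted p = 0.188). In all, 129 regions were higher, 13 lower and 175 did not pass (limma, median log2 0.44), and 4, 5 and 20 were lower without fructose replicate 1, fructose replicate 2 and acetate replicate 1. The 96 regions bound on acetate alone, chosen by their acetate signal, gave 71 of the 129 rises and 0 falls. Next to textbook Cra genes 13 of 15 were higher and 1 lower (median 2.72, and 2.30 and 2.24 under the other scalings). Regions with highly transcribed genes had a median of 0.45, which turned to -0.02 with the median of ratios. Total signal moved the median of all regions to 0.03 and gave 97 higher and 54 lower, and the median of ratios moved it to -0.03 with 90 and 60.

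The RpoB libraries ask which genes change their polymerase occupancy on acetate when Cra is missing. Signal over fruB rose 46.3-fold in Δcra, from 1.16 times the median bin in wild type to 59.5 ± 18.5 (SD, n = 2; log2 5.53, SE 0.24, limma adjusted p = 1.35e-05), and its operon partners fruK and fruA rose 43.3-fold and 36.0-fold. adhE rose 15.8-fold, from 2.03 to 33.7 ± 5.46 (limma adjusted p = 1.35e-05), and epd 12.9-fold, from 3.16 to 42.3 ± 7.82 (limma adjusted p = 3.27e-05). In the other direction, ppsA signal was 6.73-fold lower in Δcra, at 0.598 ± 0.0189 after 4.60 (log2 -2.75, SE 0.11, limma adjusted p = 1.35e-05). The lone wild-type library is assumed to vary like the other groups, here and in the comparison of Δcrp with wild type. Those groups did not vary alike: the median SD of log2 signal was 0.104 in Δcra and 0.0478 in Δcrp.

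Other large rises were at the copper efflux genes cusC (log2 2.92) and cusF (2.17) and their regulator gene cusR (1.75), at fbaA, fructose bisphosphate aldolase (2.07), at cpxP, of the envelope stress response (2.03), at yggC (2.02) and at aroF, of aromatic amino acid synthesis (2.02). Large falls were at the acid resistance genes gadB (-1.23), gadA (-1.17), gadC (-1.14), gadE (-1.06) and hdeD (-1.06), at leuB, of leucine synthesis (-1.18), and at yjaB (-1.14), bsmA (-1.04) and ndk (-0.98). gadA and gadB are near-identical, and reads of one can be placed at the other. Of the textbook Cra targets, gapA rose 2.33-fold (6.01 to 14.2 ± 2.23) and pfkA by log2 0.43, while fbp (-0.79) and icd (-0.56) fell. acs, acetyl-CoA synthetase, of the acetate and CRP-activated lists, fell too (-0.70). pykF (log2 -0.08, limma adjusted p = 0.664), ptsH (log2 -0.23, adjusted p = 0.23), aceB (log2 -0.45, adjusted p = 0.141) and pck, phosphoenolpyruvate carboxykinase (log2 -0.15, adjusted p = 0.394), did not pass.

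Of 3522 genes, 437 rose and 377 fell in Δcra against wild type, and 2708 did not pass (limma, median SE 0.13). Changes of at least 2-fold numbered 58 and 43. Scaling to total signal shifted the median of all genes by -0.21 and gave 173 rises and 184 falls, and cyclic loess gave 289 and 254. The count was 392 with genes under 2 times the median bin left out, 208 with 200 bp trimmed from both gene ends, and 1906 with the wild-type file counted as 2 libraries. Rises and falls numbered 999 and 979 without Δcra replicate 1, and 623 and 585 without replicate 2.

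Of 19 textbook Cra-repressed genes 12 rose, 0 fell and 7 did not pass in Δcra, with the same 12 adjusted over the list alone, and 11 rose and 1 fell under each of total signal, quantile and cyclic loess scaling (median log2 0.74, camera adjusted p = 4.9e-09, adjusted p = 0.489 with an estimated correlation). In glycolysis 9 rose, 1 fell and 4 did not pass of 14, pgk (2.15), fbaA, gapA and eno (0.76) among the rises, and adjusted over the list alone 9 rose and 2 fell, with 5 rises and 0 falls under total signal (camera adjusted p = 0.00289, adjusted p = 0.489 with an estimated correlation). Of 7 Cra-activated genes 0 rose, 3 fell and 4 did not pass, and adjusted over the list alone 0 rose and 4 fell, while 6 fell under each of total signal, quantile and cyclic loess scaling (median -0.53, camera adjusted p = 0.00082, adjusted p = 0.489 with an estimated correlation). Of 5 genes for gluconeogenesis and malic enzymes 0 rose, 2 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.489 with an estimated correlation). These 2, ppsA and fbp, are also among the falls of the Cra-activated list. The glycolysis rises named above are all members of the Cra-repressed list too. Among 25 iron uptake genes 17 rose, 0 fell and 8 did not pass, with rises at fepA (1.00), cirA (1.00), fes (0.99) and entC (0.97), and adjusted over the list alone 20 rose and 0 fell, with 11 rises under total signal (camera adjusted p = 4.9e-09, adjusted p = 0.489 with an estimated correlation). All 7 tested genes of fatty acid degradation fell, also adjusted over the list alone, fadB by 0.94, while 5, 6 and 4 fell under total signal, quantile and cyclic loess scaling (camera adjusted p = 0.000112, adjusted p = 0.489 with an estimated correlation). Of 26 general stress genes 1 rose, 10 fell and 15 did not pass, and adjusted over the list alone 1 rose and 11 fell (camera adjusted p = 0.000378, adjusted p = 0.489 with an estimated correlation). Of 55 CRP-activated genes 1 rose, 14 fell and 40 did not pass, tnaB (-1.06) and tnaA (-0.95) among the falls, and adjusted over the list alone 2 rose and 17 fell, with 8 falls under cyclic loess (camera adjusted p = 0.000407, adjusted p = 0.489 with an estimated correlation). Without Δcra replicate 1 and without replicate 2, 5 and 6 Cra-activated genes fell, and 23 and 24 CRP-activated genes. With an estimated correlation camera passed 0 of the 19 lists (0 also at unadjusted p under 0.05), where the preset correlation passed 9 and fry 8. Of the lists past preset camera, iron uptake, general stress and ribosomal proteins did not pass fry (fry adjusted p = 0.053, 0.053 and 0.319). Fry alone passed the phosphotransferase and peptide transport lists (fry adjusted p = 0.038 and 0.0349).

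Total signal moved the median of all genes in Δcra to -0.21, and list medians moved down with it. Ribosomal protein genes had a median of 0.19 in Δcra, turning to -0.02 with total signal, -0.15 with quantile and -0.19 with cyclic loess scaling. Of 52 members, 4 rose, 0 fell and 48 did not pass, with rises at rplU (0.87) and rpmB (0.76), where total signal gave 1 rise and 0 falls, quantile scaling 3 and 17, and cyclic loess 1 and 12. Rises numbered 34 without Δcra replicate 1, 14 without replicate 2, and 0 without either Δcrp library (limma, 3 at unadjusted p under 0.05). Adjusted over the list alone 0 passed with limma (camera adjusted p = 0.00232, adjusted p = 0.799 with an estimated correlation). The mean signal over rRNA genes, which were not tested, was 12.4 times the median bin in wild type, 16.6 and 21.9 in Δcra, and 10.9 and 10.3 in Δcrp. The remaining lists did not pass camera. Of 17 TCA cycle genes 2 rose, 2 fell and 13 did not pass, with 0 and 1 under total signal, 1 and 6 under quantile and 1 and 3 under cyclic loess scaling (median 0.13, turning to -0.08, -0.22 and -0.14, camera adjusted p = 0.636). Of 20 phosphotransferase genes 3 rose, 4 fell and 13 did not pass, with 8 falls under quantile scaling (median -0.12, mean 0.67, fry upward with adjusted p = 0.038, camera adjusted p = 0.826). Of 11 for acetate use and glyoxylate shunt 0 rose, 2 fell and 9 did not pass, while 6, 6 and 5 fell under total signal, quantile and cyclic loess scaling (camera adjusted p = 0.161). Of 13 for Entner-Doudoroff and pentose phosphate 1 rose, 1 fell and 11 did not pass, with 0 of either under total signal and cyclic loess (camera adjusted p = 0.39). Of 30 respiratory genes 2 rose, 0 fell and 28 did not pass, with 3 falls under quantile scaling (median 0.14, turning to -0.07 with total signal, camera adjusted p = 0.126). Of 75 for amino acid biosynthesis 9 rose, 12 fell and 54 did not pass, with 2 rises and 10 falls under total signal (camera adjusted p = 0.783). Of 9 for flagella 0 rose, 2 fell and 7 did not pass, with 1 fall under cyclic loess (median -0.18, turning to 0.02 there, camera adjusted p = 0.283). Of 13 for anaerobic fermentation 2 rose, 4 fell and 7 did not pass, with 1, 2 and 0 falls under total signal, quantile and cyclic loess scaling (median -0.41, mean 0.01, camera adjusted p = 0.208). Of 27 for peptide transport 0 rose, 6 fell and 21 did not pass, and total signal brought the list past camera (adjusted p = 0.0254, after 0.0846). Adjusted over the list alone, rises and falls were 2 and 2 for TCA, 3 and 4 for phosphotransferase, 0 and 2 for acetate use, 12 and 16 for amino acid biosynthesis, and 2 and 8 for anaerobic genes, with no change for the rest. Of 15 heat shock genes 0 passed limma, over all genes or adjusted over the list alone, with 2 at unadjusted p under 0.05 (median 0.03, mean -0.02, turning to a median of -0.18, -0.14 and -0.16 with total signal, quantile and cyclic loess, where 0, 1 and 1 fell, camera adjusted p = 0.932, fry adjusted p = 0.873). Without Δcra replicate 1, rises and falls numbered 18 and 2 among respiratory genes, 8 and 3 in the TCA cycle, 23 and 21 in amino acid biosynthesis, 7 and 5 in the phosphotransferase system, 4 and 9 in peptide transport, 3 and 5 in acetate use, 3 and 8 among anaerobic genes, and 4 and 2 among heat shock genes. They numbered 5 and 3, 2 and 3, 15 and 20, 3 and 7, 1 and 9, 0 and 6, 2 and 7, and 0 and 2 without replicate 2, where the medians turned to 0.02 for amino acid biosynthesis and -0.08 for heat shock. Peptide transport had 2 falls without either Δcrp library.

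**Figure D3:**
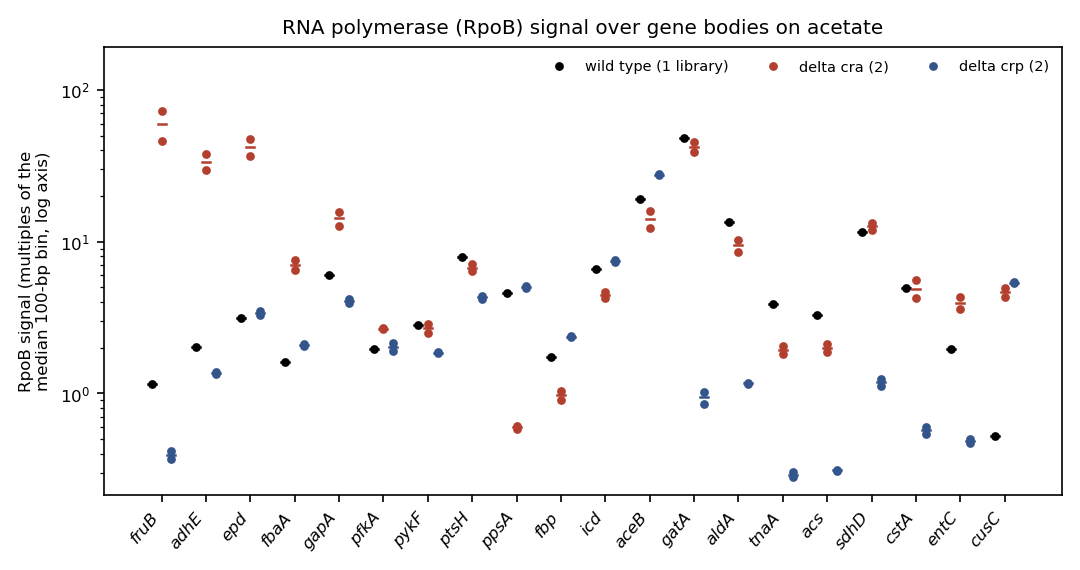
RpoB signal over 20 genes in each of the 5 distinct libraries, as multiples of the median bin on a log axis, with 1 point per library and a bar at the mean, coloured by strain. fruB stands at 1.16 in wild type and a mean of 59.5 in Δcra, ppsA at 4.60 and 0.598, and gatA at 48.0 in wild type and 0.942 in Δcrp.

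The next comparison asked the same of CRP. Among the largest falls in Δcrp were genes for carbon sources other than glucose. gatA, of galactitol uptake, fell from 48.0 in wild type to 0.942 ± 0.122 in Δcrp (SD, n = 2; log2 -5.53, SE 0.17, limma adjusted p = 1.63e-06). rbsD, of ribose use (log2 -3.64), aldA, aldehyde dehydrogenase (-3.41), and tnaA (-3.34) fell, as did sdhD, of succinate dehydrogenase (11.5 to 1.18 ± 0.0815, log2 -3.18), yqeF (-3.06), mepS, a cell wall hydrolase gene (-2.94), and cstA, a starvation-induced transporter gene (-2.91). acs fell from 3.30 to 0.313 ± 0.00339 (log2 -3.04, limma adjusted p = 3.99e-06), with its operon partners yjcH (-3.21) and actP (-2.72). The largest rise was at yjcB, 13.5-fold from 1.51 to 21.6 ± 0.483 (limma adjusted p = 4.36e-06), followed by cusC (log2 3.13), azuR (3.01), proP, an osmoprotectant transporter (2.91), psiE (2.82) and cusF (2.62). fruB (-1.35), ptsH (-0.86), pykF (-0.59), gapA (-0.55) and adhE (-0.54) fell, and fbp rose (0.42). ppsA (0.12), pfkA (0.05), icd (0.18) and aceB (0.52) did not pass (limma adjusted p = 0.377, 0.72, 0.277 and 0.0681).

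In Δcrp against wild type, 890 genes rose, 938 fell and 1694 did not pass (limma). Changes of at least 2-fold numbered 113 and 278. Scaling to total signal gave 764 rises and 716 falls, so that rises became more frequent, and cyclic loess gave 900 and 948. With genes under 2 times the median bin left out the count was 756, and with both gene ends trimmed 1074. Rises numbered 549 without Δcrp replicate 1 and 547 without replicate 2, with 724 and 741 falls.

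Of 55 CRP-activated genes 4 rose, 40 fell and 11 did not pass, and adjusted over the list alone 5 rose and 42 fell (median log2 -0.88, camera adjusted p = 1.78e-11, adjusted p = 0.25 with an estimated correlation). Of 17 TCA cycle genes 1 rose, 14 fell and 2 did not pass, with sdhC (-3.18) and sucA (-2.48), the same adjusted over the list alone (camera adjusted p = 3.39e-06, adjusted p = 0.662 with an estimated correlation). Of 30 genes of the respiratory chain and ATP synthase 0 rose, 22 fell and 8 did not pass, atpB (-1.94) and atpA (-1.83) among the falls, and adjusted over the list alone 0 rose and 23 fell (camera adjusted p = 1.8e-08, adjusted p = 0.723 with an estimated correlation). Of 20 phosphotransferase genes 1 rose, 13 fell and 6 did not pass, gatB (-5.40) and manX (-1.43) among the falls, the same adjusted over the list alone (camera adjusted p = 2.49e-05, adjusted p = 0.25 with an estimated correlation). All 7 tested fatty acid degradation genes fell, also adjusted over the list alone, fadB by 2.15. The list passed camera (adjusted p = 1.74e-05), but not with an estimated correlation (camera adjusted p = 0.27). Of 27 peptide and amino acid transport genes 0 rose, 24 fell and 3 did not pass, with argT (-1.42) and hisJ (-1.36), and adjusted over the list alone 1 rose and 24 fell (camera adjusted p = 6.52e-07, adjusted p = 0.25 with an estimated correlation). Among 25 iron uptake genes 1 rose, 15 fell and 9 did not pass, entC (-1.82) and fes (-1.75) among the falls, the same adjusted over the list alone (camera adjusted p = 0.000171, adjusted p = 0.738 with an estimated correlation). Of 75 amino acid biosynthesis genes 12 rose, 38 fell and 25 did not pass, ilvB (-2.01) and metA (-1.38) among the falls, and adjusted over the list alone 14 rose and 38 fell (camera adjusted p = 0.00775, adjusted p = 0.662 with an estimated correlation). Among 26 general stress genes 13 rose, 5 fell and 8 did not pass, with rises at otsB, of trehalose synthesis (1.25), and osmC (1.21), and adjusted over the list alone 14 rose and 5 fell (camera adjusted p = 0.047, adjusted p = 0.816 with an estimated correlation). This call was lost with total signal (camera adjusted p = 0.0818), and 8 fell under cyclic loess. Without Δcrp replicate 1 and without replicate 2, 5 and 6 amino acid biosynthesis genes rose, and 3 and 3 general stress genes fell. With an estimated correlation 0 lists passed camera (3 at unadjusted p under 0.05), against 9 with the preset one and 10 with fry. General stress did not pass fry (fry adjusted p = 0.08), while acetate use and flagella passed fry alone (fry adjusted p = 0.0491 and 0.0352).

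The other lists did not pass camera. Of 52 ribosomal protein genes 3 rose, 10 fell and 39 did not pass, rpmF (-0.89) and rplC (-0.82) among the falls, and adjusted over the list alone 0 rose and 4 fell, while falls numbered 15, 29 and 34 under total signal, quantile and cyclic loess scaling. Of the 14 glycolysis genes 2 rose, 4 fell and 8 did not pass, with 1 rise under cyclic loess (median 0.05, turning to -0.09 there), and of 19 Cra-repressed genes 3 rose, 7 fell and 9 did not pass, with 1 rise under cyclic loess (median -0.06, turning to 0.03 with quantile scaling). Of 7 Cra-activated genes 2 rose, 1 fell and 4 did not pass, with 4 rises under total signal and quantile scaling, and of 11 acetate genes 2 rose, 5 fell and 4 did not pass, with 4 rises and 4 falls under quantile scaling. Of 5 gluconeogenesis genes 1 rose, 2 fell and 2 did not pass, with 2 rises under quantile and cyclic loess scaling (median 0.12, turning to -0.01 with cyclic loess). The camera adjusted p was 0.415 for ribosomal proteins, and 0.763, 0.477, 0.406, 0.406 and 0.763 for the lists named after them, in that order. Of 13 for Entner-Doudoroff and pentose phosphate 3 rose, 4 fell and 6 did not pass, with 2 falls under total signal (median -0.09, turning to 0.02 with quantile scaling), and of 9 for flagella 1 rose, 5 fell and 3 did not pass, with 2 falls under total signal and 3 under cyclic loess. Of 13 anaerobic genes 4 rose, 7 fell and 2 did not pass, with 3, 3 and 2 falls under total signal, quantile and cyclic loess scaling, and of 15 heat shock genes 0 rose, 3 fell and 12 did not pass, with 5 falls under cyclic loess. Their camera adjusted p was 0.748, 0.376, 0.622 and 0.44. Adjusted over the list alone, 1 glycolysis gene rose and 4 fell, and the counts of the others did not change. Ribosomal rises and falls numbered 0 and 3 without Δcrp replicate 1 (limma, 0 rises at unadjusted p under 0.05), 0 and 4 without replicate 2 (1 rise at unadjusted p under 0.05), and 13 and 23 without either Δcra library. Without Δcrp replicate 1 and without replicate 2, 1 and 2 anaerobic, 2 and 2 glycolysis, and 1 and 1 heat shock genes fell. Without either Δcra library, 5 Cra-activated and 5 acetate genes rose, and 6 heat shock genes fell. Median and mean differed in sign for glycolysis (0.05 and -0.09) and gluconeogenesis (0.12 and -0.33).

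Comparing the deletions directly needs no wild-type library. Signal in Δcra was 118-fold that in Δcrp at fruB (59.5 ± 18.5 against 0.395 ± 0.0355, SD, n = 2; limma adjusted p = 5.19e-07). It was also higher at gatB (log2 5.68), adhE (4.52), epd (3.58), rbsD (3.34), sdhD (3.31), aroF (3.25), yqeF (3.21), mepS (3.17) and nrdI, of a ribonucleotide reductase operon (3.16). acs (2.34), gapA (1.77) and pck (1.71) were higher too. Signal was lower in Δcra at yjcB (log2 -3.94), ppsA (-2.87), psiE (-2.64), azuR (-2.48), proP (-2.36), drpB (-2.20), leuC (-2.06), fbp (-1.21), aceB (-0.98) and icd (-0.74). In all, 811 genes were higher in Δcra, 731 lower and 1980 did not pass (limma, median SE 0.10). Scaling to total signal shifted the median of all genes by -0.18 and gave 464 higher and 1168 lower, and quantile normalization gave 717 and 999. Higher and lower genes numbered 548 and 412 without Δcrp replicate 1, and 549 and 372 without Δcrp replicate 2. The count was 676 with low genes left out and 888 with gene ends trimmed.

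Of the lists, respiratory chain and ATP synthase genes were higher in Δcra in 28 of 30 cases (camera adjusted p = 1.08e-11, adjusted p = 0.345 with an estimated correlation), iron uptake in 22 of 25 (camera adjusted p = 5.51e-12, adjusted p = 0.345 with an estimated correlation), CRP-activated genes in 36 of 55 with 3 lower (camera adjusted p = 6.28e-10, adjusted p = 0.212 with an estimated correlation) and Cra-repressed genes in 15 of 19, with 0 lower, and 2, 2 and 1 lower under total signal, quantile and cyclic loess scaling (camera adjusted p = 8.58e-08, adjusted p = 0.345 with an estimated correlation). General stress genes were lower in 23 of 26, dps (-1.44) and otsB (-1.43) among them (camera adjusted p = 1.27e-08, adjusted p = 0.345 with an estimated correlation), and Cra-activated genes in 6 of 7 with 1 higher (camera adjusted p = 0.00241, adjusted p = 0.345 with an estimated correlation). Higher and lower genes numbered 13 and 2 of 17 in the TCA cycle (camera adjusted p = 4.57e-07, adjusted p = 0.345 with an estimated correlation), 14 and 1 of 20 in the phosphotransferase system (camera adjusted p = 4.57e-07, adjusted p = 0.212 with an estimated correlation), 18 and 1 of 27 in peptide transport, 11 and 1 with total signal (camera adjusted p = 3.16e-06, adjusted p = 0.212 with an estimated correlation), and 9 and 1 of 14 in glycolysis, 6 and 2 with total signal (camera adjusted p = 0.00152, adjusted p = 0.345 with an estimated correlation). They numbered 34 and 6 of 75 in amino acid biosynthesis, 20 and 12 with total signal and 33 and 10 with quantile scaling (camera adjusted p = 0.000705, adjusted p = 0.345 with an estimated correlation), and 7 and 0 of 7 in fatty acid degradation (camera adjusted p = 7.61e-05, adjusted p = 0.33 with an estimated correlation). Among 52 ribosomal proteins they numbered 19 and 0, with 10 and 3 under total signal, 15 and 10 under quantile and 24 and 1 under cyclic loess scaling (camera adjusted p = 2e-05, adjusted p = 0.597 with an estimated correlation). The ribosomal proteins higher in Δcra numbered 46 without Δcra replicate 1, 29 without Δcra replicate 2, 2 without Δcrp replicate 1 and 4 without Δcrp replicate 2. Adjusted over the list alone, the counts were 38 higher and 4 lower for CRP-activated, 14 and 2 for TCA, 36 and 9 for amino acid biosynthesis, 22 and 1 for peptide transport, 23 and 0 for iron uptake, 14 and 0 for ribosomal proteins, 6 and 3 for acetate use and 4 and 3 for Entner-Doudoroff and pentose phosphate, with no change for the rest. Gluconeogenesis, acetate use, Entner-Doudoroff and pentose phosphate, flagella, anaerobic and heat shock lists did not pass (camera adjusted p = 0.441, 0.217, 0.951, 0.525, 0.171 and 0.293). The anaerobic list had a median of -0.25 and a mean of 0.13. With an estimated correlation 0 lists passed camera (3 at unadjusted p under 0.05), against 13 with the preset one and 14 with fry. Ribosomal proteins did not pass fry (fry adjusted p = 0.0988), while gluconeogenesis and acetate use passed fry alone (fry adjusted p = 0.0127 and 0.0479).

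Set side by side, 288 genes rose and 264 fell in both deletions against wild type, and 48 changed in opposite directions. cusC, cusF and fadB were among those that changed the same way, and fruB, adhE, gapA, fes and fbp among the opposite ones. Independent lists of these sizes would share 110 rises and 100 falls. Simulated unchanged groups against the same wild-type library shared 0.16 calls per direction on average. Across genes, which are not independent replicates, the fold changes correlated at 0.455, where the simulation gave 0.667 from the shared library alone. Their covariance was 0.150, and the simulated one 0.0136. The counts of 110 and 100 leave out the shared library and the simulation leaves out real effects. Part of the excess of shared calls may come from the shared wild-type library, which cannot be split. The number changed the same way was 552, 358 under cyclic loess and 232 under total signal. It was 1315 without Δcra replicate 1 and 868 without replicate 2, and 172 and 177 rose in both without Δcrp replicate 1 and without replicate 2. Genes changed in opposite directions numbered 201 without Δcra replicate 1 and 123 without replicate 2.

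**Figure D4:**
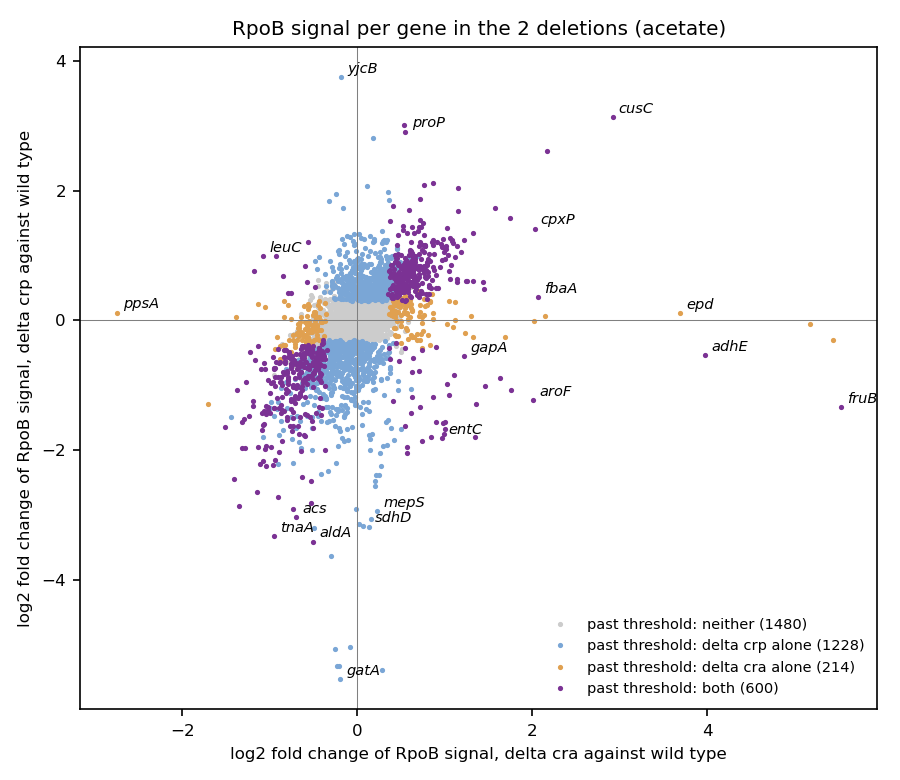
Log2 fold change of RpoB signal in Δcra against wild type (horizontal) and Δcrp against wild type (vertical), with 1 point per gene, coloured by whether it passed the threshold in neither comparison (1480 genes), in Δcrp alone (1228), in Δcra alone (214) or in both (600). fruB lies far to the right and gatA far down.

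Binding and occupancy were then joined for acetate, to ask whether genes next to Cra regions change without Cra. fruB, with 5388 ± 847 at its region, epd and adhE rose in Δcra, and ppsA, with 21.2 ± 4.41, fell, as did fbp, icd, tnaB and tnaA. pykF (176 ± 38.7), ptsH (2243 ± 400.1) and aceB (62.2 ± 8.07) lay next to enriched regions and did not pass in Δcra. Of 522 tested genes next to an acetate region, 129 changed (24.7%), 86 rising and 43 falling, against 685 of 3000 other genes (22.8%), while rises and falls turned to 80 and 121 with quantile and 50 and 90 with cyclic loess scaling, and numbered 49 and 39 with total signal, 213 and 124 without Δcra replicate 1, and 144 and 76 without replicate 2. The odds ratio was 1.11 (two-sided Fisher's exact test, p = 0.368). By the same exact test it passed with each other scaling, at 2.06 with total signal (p = 2.43e-07), 1.89 with quantile (p = 3.13e-10) and 2.36 with cyclic loess (p = 2.33e-13). It was 1.51 without Δcra replicate 1 (exact p = 2.55e-05), 1.48 without Δcra replicate 2 (exact p = 6.22e-05) and 0.993 with regions of at least 10-fold enrichment (exact p = 1). With acetate regions that hold no highly transcribed gene the odds ratio was 1.315 (exact p = 0.0546). The other genes and the random sets were not matched on signal level, so these tests cannot tell binding from level. Of 165 highly transcribed genes next to regions that hold such genes, 85 changed with quantile and 64 with cyclic loess scaling, after 37 in the main fit. The median log2 change of the 522 genes was 0.10, where 95% of random sets lay between -0.05 and 0.02 (permutation p = 0.0001, the smallest that 10000 sets can give), and it turned to -0.12 with cyclic loess, -0.11 with quantile scaling and -0.11 with total signal, which moved the median of all genes to -0.21.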

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

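The look at bins covered in 1 glucose library and the counts of opposite genes under other settings were chosen only after the data were seen, and the limma tests across genes were planned. The effects of the deletions differed in direction at 38 genes, which were higher in Δcra and lower in Δcrp than in wild type. These genes also differed between Δcra and Δcrp by limma, which follows from the opposite changes and adds no support. They included fruB (log2 5.53 in Δcra and -1.35 in Δcrp), adhE (3.98 and -0.54), gapA (1.22 and -0.55), the iron uptake genes fes (0.99 and -1.75), entC (0.97 and -1.82), cirA (1.00 and -1.67) and fepA (1.00 and -1.58), the ribonucleotide reductase genes nrdH, nrdI, nrdE and nrdF, and aroF and tyrA of aromatic amino acid synthesis. The opposite pattern held at 10 genes, lower in Δcra and higher in Δcrp. These were the leucine synthesis genes leuA, leuB, leuC and leuD, fbp (-0.79 and 0.42), dps, csgE, treF, guaA and yoeG. In place of 38 and 10 genes, 135 and 66 were counted without Δcra replicate 1, 77 and 46 without replicate 2, 26 and 15 with total signal, 38 and 26 with quantile and 44 and 21 with cyclic loess scaling, 33 and 29 with low genes left out, 16 and 5 with trimmed gene ends, and 116 and 78 with the wild-type file counted as 2 libraries. Of the 48 genes, 48, 48, 30, 39, 37, 26, 21 and 48 were among them.

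In Cra glucose replicate 2, 8.87% of the signal lay in bins without a read in the other glucose and both fructose libraries. These were 961 bins, and 304 of them overlap rRNA genes. The mean over rRNA genes in glucose replicate 2 was 17.3 times the median bin. It was 0.0613 in the other glucose library and 0.0569 to 0.0896 across the other Cra libraries. The extra signal counts toward that library's total, and so enters the comparisons with glucose under scaling to total signal.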

How the results depend on the processing

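Chosen only after the data were seen were the tests with trimmed or shifted gene bodies, cyclic loess, the wild-type file counted as 2 libraries, crossed replicate numbers, the summit bin, the gene lists, region classes and shared changes without each library, opposite changes under each fit, and the joined test with total signal or quantile scaling and with regions without highly transcribed genes or higher on acetate than fructose. Of 164 main values recomputed, 123 stayed on the same side of their threshold and in the same direction, or within 1.5 times for a count. Where a value below moved, the cause was not tested unless a reason is given. Of 6200 recomputed values of single genes and regions, 5887 did not change their call, 279 lost it, 25 gained one and 9 turned in direction.

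Cra regions numbered 495 on glucose, 458 on fructose and 669 on acetate at 3-fold enrichment, and 83, 75 and 128 at 10-fold, by construction of the threshold. Acetate had 561 with bins of 50 bp, and 449 to 506 when a single library decided, which asks less of the data. With only regions of at least 10-fold enrichment, of which there are fewer, 82 changed between acetate and glucose and 75 between acetate and fructose. Leaving out each library gave 22 to 58 changed regions for fructose against glucose. At 10-fold enrichment 13 pairs of list and carbon source passed in place of 20.

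For Δcra against wild type, 357 genes passed with total signal, 392 with genes under 2 times the median bin left out, 208 with gene ends trimmed, 101 with a 2-fold limit, 1906 with the wild-type file counted as 2 libraries, and 721 to 1978 with each library left out in turn. Of the 814 genes called, 329 kept their call with total signal, 423 with cyclic loess, and 200 of the 481 still tested with trimmed gene ends. For Δcrp against wild type, 756 passed with the stricter filter, 1074 with trimmed ends and 391 with the 2-fold limit. For Δcra against Δcrp these were 676, 888 and 258, and leaving out each library gave 921 to 2112. The filter and the trimming leave fewer genes to test. A left-out library leaves its group with 1, so the spread comes from the pair of the other deletion. Without a Δcra library this is the smaller spread of Δcrp, and without a Δcrp library the larger spread of Δcra. With an estimated correlation camera passed 0, 0 and 0 lists in the 3 comparisons (0, 3 and 3 at unadjusted p under 0.05), where fry passed 8, 10 and 14.

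For genes next to Cra regions the odds ratio turned to 0.993 with regions of at least 10-fold enrichment. It passed the threshold at 1.42 with regions higher on acetate than on fructose, at 2.06, 1.89 and 2.36 with total signal, quantile and cyclic loess scaling, and at 1.48 to 1.51 with each Δcra library left out. With regions that hold no highly transcribed gene the odds ratio was 1.315 and did not pass (Fisher's exact p = 0.0546). None of these comparisons was matched on signal level. The median log2 change turned to -0.12 with cyclic loess. Genes changed the same way in both deletions numbered 232 with total signal and 358 with cyclic loess, and the covariance was 0.0654 without the genes changed in both, which that choice removes. Among named genes that had not passed, the log2 change of pykF in Δcra turned to 0.0498 without a filter and 0.0125 with trimmed ends, and ran from -0.175 to 0.0222 with each library left out. In Δcrp, ppsA turned to -0.0468 with the stricter filter and -0.00788 with cyclic loess, pfkA to -0.108 and -0.0832, and icd to -0.0256 with cyclic loess. With each library left out pfkA ran from -0.0255 to 0.134.

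No pairing by replicate number was seen, though so few libraries cannot exclude it. Deviations of same-numbered libraries correlated at -0.13 for RpoB, and at -0.06, 0.01 and -0.03 for Cra. With the number as a replicate block, 163, 47 and 136 regions changed for acetate against glucose, fructose against glucose and acetate against fructose, and 1090, 1786 and 1591 genes for Δcra against wild type, Δcrp against wild type and Δcra against Δcrp. Under the block the phosphotransferase list passed camera in Δcra (adjusted p = 3.8e-07, after 0.826) and acetate use in Δcrp (0.0257, after 0.406), amino acid biosynthesis in Δcrp did not (0.0554, after 0.00775), and no other list call moved. Under the block 758 genes changed the same way in both deletions, and the odds ratio next to Cra regions was 1.01. With crossed numbers in Δcrp the gene counts were 1371, 2018 and 1801. Not run were a count test by another tool, since coverage is not counts, the motif searches and the joined test on motif sites, for which no genome was used here, gene bodies without their first 200 bp, since the gene table gives no strand, and leaving out the wild-type library, of which there is 1. The tests planned on gene starts or on first downstream genes were run with either gene end, since strand is not given. At this depth, changes of log2 1 in Cra regions were recovered in part on simulated data.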

Other observations

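The tests of a constant scaling difference on acetate, of cyclic loess, of the odds ratio of highly transcribed genes under other settings and of the number of wild-type libraries were chosen only after the results were seen. Some genes next to acetate regions that no list holds changed in Δcra, and were chosen after their values were seen. setB, a sugar efflux gene at the fruB region, rose 3.09-fold, lpxP, of lipid A synthesis, 2.36-fold, and aroL, of aromatic amino acid synthesis, 2.35-fold. ppc, phosphoenolpyruvate carboxylase, rose 1.77-fold, and fieF, a metal efflux gene next to pfkA, 1.86-fold. ppsR, the regulator of phosphoenolpyruvate synthase next to ppsA, had a log2 change of -0.91. At acetate regions of at least 10-fold enrichment without highly transcribed genes, the coverage borders on the 2 strands lay a median of 44.5 bp apart (quartiles 29.8 and 91.8 bp, n = 68). With highly transcribed genes it was 58.5 bp (quartiles 32 and 134 bp, n = 50). Outside the deleted genes, long stretches with almost no reads lay in Δcra replicate 2. They spanned positions 1372204 to 1372743 in ycjP (540 bp), 1547337 to 1548087 in fdnG (751 bp) and 2567501 to 2568035 over eutG and eutJ (535 bp).

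More Cra regions were bound on acetate than on the other carbon sources, 283 against 204 and 197. Chance in sparse libraries is argued against: outside glucose and fructose regions, 146 bins reached 5-fold enrichment in both acetate libraries, where independent libraries would share 5.42. A constant scaling difference as the whole cause is argued against too, since regions next to textbook Cra genes had a median log2 change 0.933 above regions with highly transcribed genes (1.42, n = 10, against 0.49, n = 97; two-sided permutation p = 0.0121, across regions, which are not independent replicates). How many regions rise stays open. Scaling by the median of ratios gave 83 higher and 64 lower, and the regions were chosen by their signal in these same libraries. A candidate explanation for the rise at textbook targets is stronger Cra binding during growth on acetate, which was not tested apart from the quality of these libraries.

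Many Cra regions lay in highly transcribed genes. Pull-down that follows transcription is a candidate explanation: across 102 such regions, Cra enrichment on acetate rose with wild-type RpoB signal (Spearman's rho 0.631, across regions of the same libraries). Whether Cra binding acts on these genes on acetate stays open: 37 of 165 highly transcribed genes next to these regions changed in Δcra, against 14 of 33 next to no acetate region (odds ratio 0.392, two-sided Fisher's exact p = 0.0274). Of 19 other fits, by the same exact test, 10 kept the odds ratio under 1 and past the threshold (0.202 to 0.436), 7 had it under 1 without passing, among them 0.46 with total signal (p = 0.0789), 0.691 with quantile (p = 0.445) and 0.596 with cyclic loess scaling (p = 0.181), and in 2 it was above 1 without passing, 1.26 without Δcra replicate 1 (p = 0.675) and with no finite value for trimmed gene ends. The bound set beforehand, an odds ratio of at most 1, does not exclude such binding, because 14 genes changed with no region nearby, so that changes elsewhere can hide an effect at bound genes, and no untagged library was used here.

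Genes changed the same way in both deletions were more than independent lists would share, 288 rises and 264 falls against 110 and 100. A level-dependent difference of the wild-type library is argued against only as the whole cause. After cyclic loess the covariance was 0.121, above 0.0150, the highest of 100 simulated draws without effect. The draws were not scaled by cyclic loess and held no real effect, so any true effect common to both deletions would lie above them. What share of the changes a level-dependent difference makes up stays open. The wild-type values come from 1 distinct library, so a shared response to losing either regulator cannot be told apart from a deviation of that library. A hypothesis is that part of the shared changes may belong to a response common to both deletions, and a separate wild-type library would test it.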
